A study of Homo sapiens with 23 samples.

How the data were processed

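Replication start sites and chromatin binding were mapped by sequencing in 2 established human cell lines, HCT116 (colon carcinoma) and K562 (chronic myelogenous leukemia). Start sites were mapped as nascent strands, short newly made DNA that resists λ-exonuclease because it still carries an RNA primer. Binding was mapped by ChIP-seq with antibodies to SIRT1 phosphorylated at T530 (pSIRT1), to MCM2 phosphorylated at S139 (pMCM2) and to histone H4 acetylated at lysine 16 (H4K16ac). The 23 samples each formed a group of 1 library, so there were no replicates and no p-values were computed. Peak lists of 21 samples were analysed. The 2 sheared genomic DNA controls were not analysed here.

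Coordinates were on hg19, per the submitters' processing notes, which also name MACS and SICER without versions or settings. Sheared genomic DNA of the same cell line served as the control for peak calling, per the labels. The aligner, thresholds and filters are not given in the sources used here. The lists have no column names, and units were inferred from their values and layout. For 18 lists the authors deposited whole numbers per region that were taken as read counts, not scaled between libraries. These regions lay on a 200 bp grid, except that the ends of the HCT116 pSIRT1 regions were 1 bp short of it. The K562 pSIRT1 lists of middle S and G2 hold a decimal score per region deposited by the authors, which was not read as a count. The HCT116 H4K16ac list has the layout of MACS output, and its deposited columns hold a peak score, a fold enrichment and −log10 p and q values as the authors' caller wrote them. Scores and counts are the authors' own values per peak and were used to rank or filter peaks within a list. Reads at peaks shared by 2 lists were compared as a log2 ratio relative to the rest of the genome. Counts were also summed per list and per kb, and the median count of a reference list served as a limit for other lists. These sums and limits were not scaled for depth, which is unknown. The fold enrichment and −log10 columns of the authors' H4K16ac list were not used further.

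Overlapping peaks within a list were merged, and peaks on chromosomes 1 to 22 and X were kept. For lists A and B, the number of peaks of A that shared at least 1 bp with B was divided by the mean number over 200 relocations of the peaks of A, each moved to a random place 50 to 500 kb away with its width kept. A value of 0.5 was added to both numbers before the logarithm. This fold takes account of peak widths and regional densities, but it still depends on list length and is limited where relocated peaks already overlap often, so folds of different lists are not on a strictly common scale. Intervals of 95% came from 1000 resamplings of the 599 genome blocks of 5 Mb. A fold was called where its interval excluded 1, and a difference of log2 folds where its interval excluded 0. The intervals cover the spread along the genome in these libraries and not the spread between cultures. Peak numbers were compared as ratios with the same intervals. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

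The overlap procedure was tested on simulated data for the comparison of the 121730 HCT116 pSIRT1 peaks with the depleted list. In a first version the second list was moved by 50 to 500 kb, the range of the relocations themselves, with nothing planted. Then 12 of 20 runs were called with folds between 0.987 and 1.00. Peaks relocated over the same range can meet again the moved depleted-list peaks that they first overlapped, but this cause was not tested. A second version, made after that result, moved the list by 1000 to 2000 kb. With nothing planted, 1 of 20 runs was then called and folds lay between 0.997 and 1.01. Folds within about 1% of 1 are therefore not read as enrichment or depletion, even where their interval excludes 1. With overlaps planted at 5, 20 and 40% of peaks, 20 of 20 runs were called at each level and the mean excess recovered was 3.88, 16.1 and 34.0%. For differences, 1 of 20 runs was called with 20% planted in both lists and 20 of 20 with 25 against 20%. Both lists of such a run were made from the depleted list and were alike in length and width. The rate of false calls for differences between unlike lists, which many comparisons below involve, was not tested.

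Before the data were examined, the comparisons, the calling rule and these alternatives were fixed: an overlap of at least 50% of the shorter peak, peaks within 1 kb of each other, the higher-scoring 50% of each list, equal list lengths, placement anywhere on the chromosome within 100 kb bins that hold a peak of any list, relocation by 5 to 50 kb, and for peak numbers a common score limit (the median of the reference list), merging within 1 kb, covered length and leaving out the 2 densest chromosomes. Using 200 bp around peak middles, odds ratios in place of folds, and leaving out chromosomes 5 and 21 were chosen after seeing the data, as were the K562 site classes by S fraction, the classes of depleted-list sites by the number of other lists that hold them, the further pairs, the 50 Mb segment end, the comparison of reads at shared peaks and the matching of sites on width and reads. With no annotation or genome of this build used here, regions are named by coordinates, 3 per list: those with the highest authors' score, and where lists are combined those whose lowest score percentile among the lists is highest. Promoter overlap, sequence content, gene lists and GC-matched relocation were not analysed here.

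Depth can be read only in part from peak lists. The reads inside called regions, 578108 in the K562 pMCM2 G1 list to 20014274 in the HCT116 SIRT1-depleted list, are not library totals. The fewest reads in a region of at most 200 bp ranged from 6 to 25 among the K562 and HCT116 count lists other than the wild-type rescue list, where it was 31, so the lists differ in the signal a region needed to be called.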

Results

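The data comprised 21 peak lists. In HCT116 cells, nascent strands were mapped in a SIRT1-depleted line, in that line with wild-type SIRT1 restored (wild-type rescue), in that line with the non-phosphorylatable mutant T530A restored (T530A rescue), and in wild-type cells treated with 200 nM aphidicolin, a DNA polymerase inhibitor, for 24 h and released for 24 h. SIRT1 is a NAD-dependent deacetylase. Unsynchronised HCT116 cells also gave ChIP lists for pSIRT1, for pMCM2, a phosphorylated form of a subunit of the replicative helicase, and for H4K16ac, a histone mark that SIRT1 can remove. In K562 cells, nascent strands were mapped in early, middle and late S fractions, and pSIRT1 and pMCM2 in G1, early S, middle S, late S and G2 fractions, with a further pSIRT1 list from unfractionated cells. Each group had 1 library and there were no replicates, so the differences below are between libraries. The folds below are overlaps relative to relocated peaks, with 95% intervals along the genome in parentheses.

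The series title names phosphorylated SIRT1 as a limit on replication initiation. The first comparison counts start sites in the depleted line, both rescue lines and the aphidicolin-treated wild-type cells, which have SIRT1. No list of nascent strands from untreated wild-type HCT116 cells was available. The ratio of the aphidicolin list therefore cannot separate the drug from the cell line or the rescue. The wild-type rescue list held the fewest HCT116 nascent-strand peaks, 74479, against 109990 in SIRT1-depleted cells, 103974 in T530A rescue cells and 96993 after aphidicolin. The ratios to the wild-type rescue were 1.48 (1.43 to 1.52), 1.40 (1.39 to 1.41) and 1.302 (1.26 to 1.33). The wild-type rescue peaks were wider, with a median of 3800 bp against 2400 bp in each of the other lists. Covered length was therefore 372.0 Mb in the wild-type rescue, 384.2 Mb in the depleted cells, 342.7 Mb in the T530A rescue and 314.3 Mb after aphidicolin. As ratios of covered length, the depleted list no longer differed from the wild-type rescue (1.03, 0.995 to 1.07), and the T530A and aphidicolin lists lay below it (0.922 and 0.845). Among peaks above the median read count of the wild-type rescue list, the ratio of the depleted list was 1.11 (1.07 to 1.15). The T530A and aphidicolin ratios were 0.920 and 0.824. This limit was not scaled for depth, and the depleted list held 52.1 reads per kb of peaks against 40.25 in the wild-type rescue. Regions of at most 200 bp held at least 31 reads in the wild-type rescue list and at least 24 or 25 in the others. Differences in depth and peak calling thus cannot be told apart from differences in start sites.

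Both rescue lists were dense on the first 50 Mb of chromosome 5 and on chromosome 21. Scaled to list totals, the wild-type rescue held 2.78 times (2.12 to 3.80) the peaks of the depleted list on the first 50 Mb of chromosome 5 and 1.80 times (1.45 to 2.15) on chromosome 21. The T530A rescue held 2.63 times (2.03 to 3.53) and 1.71 times (1.42 to 2.03). On the rest of chromosome 5 the ratios were 1.05 and 1.02. The aphidicolin list held 0.816 and 0.910 times the peaks of the depleted list on these segments. Without chromosomes 5 and 21, the peak number of the depleted list was 1.55 times that of the wild-type rescue.

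**Figure D1:**
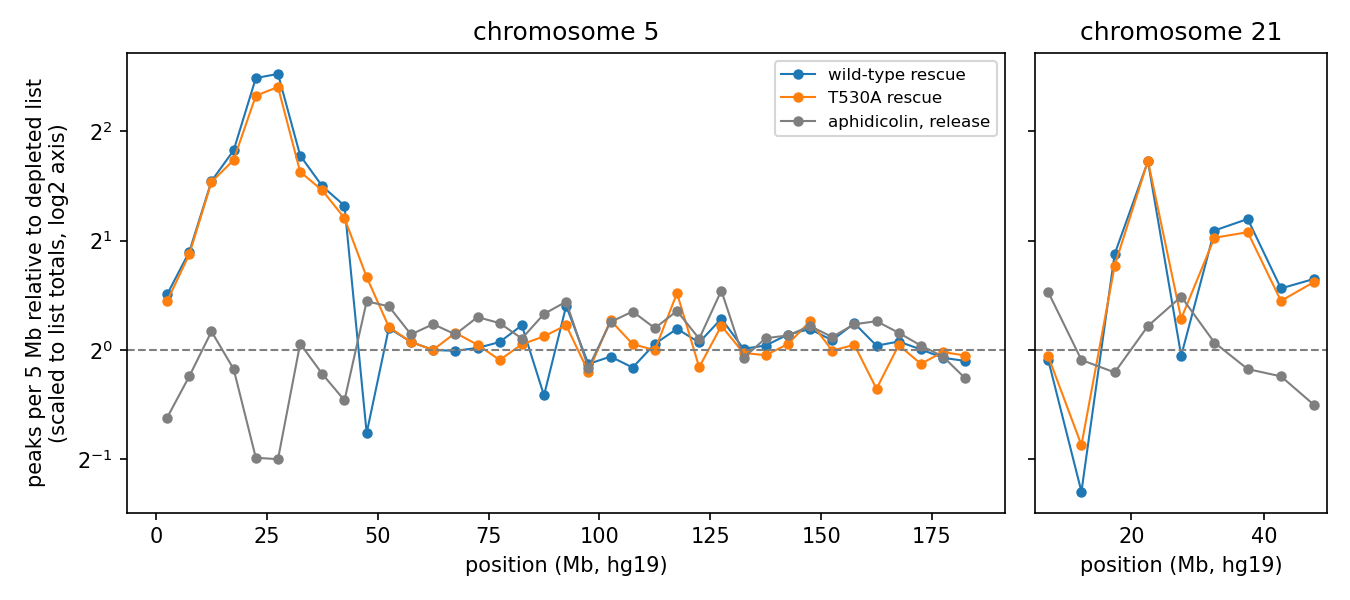
Nascent-strand peaks per 5 Mb block along chromosomes 5 and 21 (hg19), as the ratio of each HCT116 list to the depleted list after scaling to list totals, on a log2 axis. Points are blocks with at least 10 depleted-list peaks, the dashed line marks a ratio of 1, and the wild-type and T530A rescue lists reach 5.75 and 5.29 times the depleted list in the block that starts at 25 Mb of chromosome 5.

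Start sites were shared between the HCT116 lists more often than chance. Of the depleted-list peaks, 50.8% overlapped the wild-type rescue list and 56.0% the T530A list, which are folds of 1.71 (1.65 to 1.77) and 1.79 (1.73 to 1.85). The log2 fold with T530A was higher by 0.067 (0.059 to 0.076). The wild-type rescue and T530A lists overlapped with a fold of 1.92, and the aphidicolin list overlapped the wild-type rescue, depleted and T530A lists with folds of 2.02, 1.82 and 2.11. The region with the most reads in both rescue lists and after aphidicolin began at position 86726401 of chromosome 8. It ended at 86841200 in the wild-type rescue list, which counted 30095 reads there. A region of chromosome 4 between 49258201 and 49333600 came next in the wild-type rescue list with 25981 reads, and overlapping regions were among the 3 highest of the depleted, T530A and aphidicolin lists. In the depleted list the highest count, 42327 reads, was at 105201 to 112600 of chromosome 18. This region of chromosome 18 and that of chromosome 4 also ranked among the 3 highest of several ChIP lists in both cell lines, so a high read count there was not particular to nascent strands.

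Depleted-list peaks also found in the T530A list were divided by their overlap with the wild-type rescue list. Those without such an overlap are called sites without wild-type SIRT1. The name describes these lists only, since the aphidicolin list, from wild-type cells, held 48.3% of them. Of the 109990 depleted-list peaks, 54083 did not overlap the wild-type rescue list, and 17928 of these (33.1%) were in the T530A list. Among these 17928 sites, 48.3% overlapped the aphidicolin list, a fold of 1.82 (1.75 to 1.88). Among the 43716 depleted-list sites found in both rescue lists, 79.6% did, a fold of 2.17. Sites without wild-type SIRT1 thus overlapped aphidicolin sites less, by a log2 fold of -0.26 (-0.29 to -0.22), though still more than chance. The direction was the same in 9 of 9 alternatives, but the size ran from -0.15 with relocation by 5 to 50 kb to -1.38 as a log2 odds ratio. The sites in both rescue lists were selected for presence in the wild-type rescue list, which itself overlapped the aphidicolin list. A difference in this direction was therefore favoured by how the classes were made and is not read as an effect of SIRT1. The reverse class, in the depleted and wild-type rescue lists and not in the T530A list, was not analysed. The sites without wild-type SIRT1 had a median width of 2200 bp and 98 reads, those in both rescue lists 3600 bp and 170 reads. Among the sites in the depleted, T530A and aphidicolin lists and not in the wild-type rescue, the highest ranked was at 161405401 to 161445400 of chromosome 1, with 10879 reads in the depleted list. The second was at 228741401 to 228783800 of chromosome 1 with 9032 reads and the third at 17012201 to 17056800 of chromosome 1 with 3600 reads. The region that began at 228741401 also overlapped the highest-scoring region of the K562 pSIRT1 G2 list, so a high value there was not particular to nascent strands. The strongest of the 7744 peaks found in the wild-type rescue alone was at 75218601 to 75232000 of chromosome 17 with 650 reads.

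Phosphorylated SIRT1, pMCM2 and H4K16ac of HCT116 cells all lay at nascent-strand sites more often than chance. pSIRT1 peaks overlapped the wild-type rescue list at 48.7% (fold 1.64, 1.59 to 1.70), the T530A list at 53.6% (1.75, 1.69 to 1.82), the aphidicolin list at 47.9% (1.73, 1.67 to 1.78) and the depleted list at 67.8% (1.89, 1.82 to 1.97). The overlap with the depleted list exceeded that with the wild-type rescue list by a log2 fold of 0.20 (0.18 to 0.23) for pSIRT1, 0.18 (0.16 to 0.20) for pMCM2 and 0.14 (0.12 to 0.16) for H4K16ac. Of the pSIRT1 peaks, 26.0% were in all 4 nascent-strand lists and 15.99% in none of them. In pairs added after seeing the data, these ChIP lists also overlapped the early, middle and late S lists of K562. Those folds were 1.45, 1.61 and 1.53 for pSIRT1, 1.69, 1.82 and 1.78 for pMCM2 and 1.57, 1.66 and 1.60 for H4K16ac. With the HCT116 lists, pMCM2 gave 1.65 to 1.87 and H4K16ac 1.43 to 1.58. For these the overlap was thus not particular to start sites of their own cell line.

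**Figure D2:**
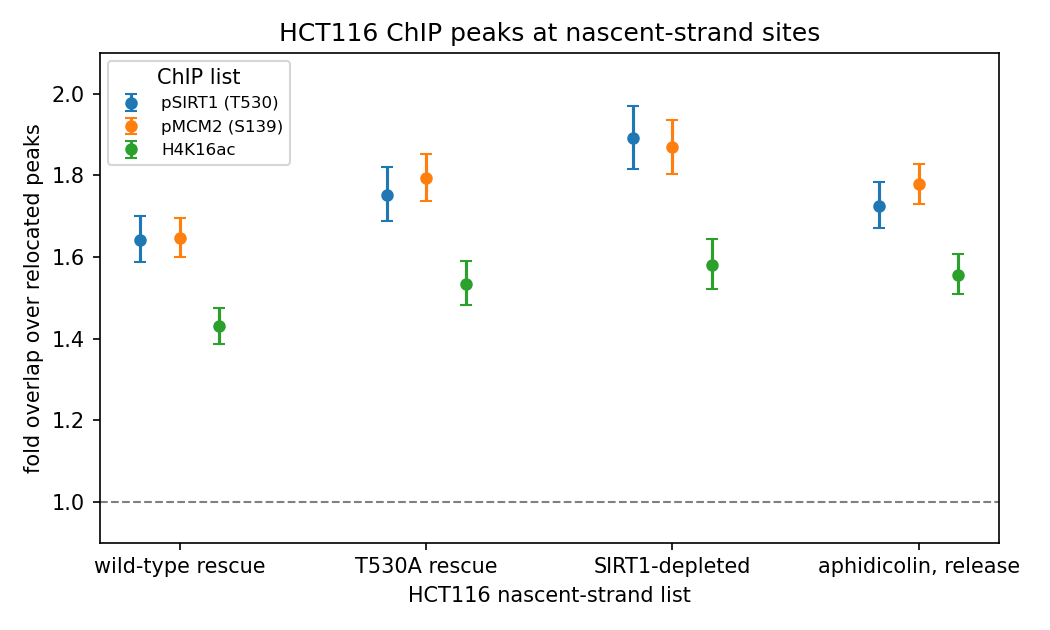
Fold overlap of HCT116 ChIP peaks with each HCT116 nascent-strand list, relative to relocated peaks, where 1 (dashed) is chance. Points are single libraries with 95% intervals from resampling 5 Mb genome blocks, and for pSIRT1 the folds run from 1.64 with the wild-type rescue list to 1.89 with the depleted list.

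At sites without wild-type SIRT1, 63.5% of sites carried a pSIRT1 peak of the unsynchronised HCT116 cells, against 78.4% of the sites in both rescue lists. The folds were in the opposite order, 2.09 and 1.90 (1.83 to 1.98), since relocated sites of these classes overlapped pSIRT1 at 30.4 and 41.2%. The difference of log2 folds was 0.14 (0.10 to 0.17) for pSIRT1, 0.16 (0.13 to 0.20) for pMCM2 and 0.19 (0.16 to 0.22) for H4K16ac. As log2 odds ratios these differences turned to -0.38, -0.12 and -0.34, so the order of the classes depended on the measure.

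The 3 HCT116 marks lay together. Of the pSIRT1 peaks, 86.4% overlapped H4K16ac (fold 1.83, 1.76 to 1.90) and 53.1% overlapped pMCM2 (1.96, 1.88 to 2.04). Of the pMCM2 peaks, 66.0% overlapped H4K16ac (1.91, 1.83 to 1.98). The pSIRT1 peaks that also ranked highest for pMCM2 were at 1010201 to 1027999 of chromosome 11 with 2497 pSIRT1 reads, at 105201 to 112399 of chromosome 18 with 3321 and at 1086201 to 1099599 of chromosome 11 with 1535. By density, pSIRT1 peaks were concentrated on chromosomes 19 and 22, at 2.44 (1.85 to 2.95) and 2.52 (2.17 to 2.86) times the genome average, and sparse on chromosome 4 at 0.490 (0.329 to 0.721). The pMCM2 density on chromosomes 19 and 22 was 1.72 and 1.84 times the average.

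In K562 cells, nascent-strand sites of the 3 S-phase fractions overlapped about 3 times as often as chance. Early S with middle S gave a fold of 3.11 (2.99 to 3.24), middle with late S 2.95 (2.84 to 3.08) and early with late S 3.03 (2.91 to 3.17). Of 73296 early S peaks 54.6% overlapped middle S and 59.7% late S. The log2 fold of early S with late S differed from that with middle S by -0.036 (-0.057 to -0.015), and the log2 odds ratios differed in the other direction, by 0.098. There were 29513 early S peaks (40.3%) with no late S overlap and 37999 late S peaks (46.4%) with no early S overlap. The strongest early S peak without late S overlap was at 61809001 to 61828800 of chromosome 7 with 1253 reads, and the strongest late S peak without early S overlap at 11068201 to 11153200 of chromosome 21 with 11674 reads. The next ones were at 127580001 to 127597800 of chromosome 10 for early S, with 1241 reads, and at 108515601 to 108573600 of chromosome 13 for late S, with 3735 reads.

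The number of K562 regions changed with the phase in different ways for the 2 antibodies. pSIRT1 had 75682 regions in G1, 36314 in early S, 25542 in middle S, 120213 in late S and 45881 in G2, ratios to G1 of 0.480 (0.463 to 0.496), 0.338 (0.319 to 0.357), 1.59 (1.55 to 1.62) and 0.606 (0.588 to 0.626). pMCM2 had 24359 regions in G1, and its ratios to G1 were 1.79 (1.76 to 1.82) in early S, 1.45 (1.40 to 1.51) in middle S, 1.76 (1.71 to 1.82) in late S and 3.40 (3.24 to 3.54) in G2. The pSIRT1 lists of middle S and G2 hold scores in place of counts. A difference in peak calling cannot be told apart from phase in their region numbers. Widths differed too. The median pSIRT1 region was 400 bp in early S, 2800 bp in middle S and 1600 to 1800 bp in G1 and late S. By covered length the pMCM2 ratios of early and late S shrank to 1.03 and 1.04 and those of pSIRT1 in early S and G2 to 0.134 and 0.304. Among regions above the median read count of the G1 list, the ratio of pSIRT1 in late S was 2.996, and those of pMCM2 in middle S and G2 were 2.56 and 6.72. Reads in pMCM2 regions rose from 578108 in G1, over 47.9 Mb at 12.1 reads per kb, to 4260082 in G2, over 132.0 Mb at 32.3 reads per kb, so signal per called region was not equal between phases. For pSIRT1, reads in regions rose from 3097598 in G1, over 171.4 Mb at 18.1 reads per kb, to 4935710 in early S, over 0.134 times that length at 215 reads per kb, while the number of regions fell.

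Both marks lay at K562 nascent-strand sites more often than chance in every phase. The pMCM2 overlap was lowest in G1 and next lowest in early S, an order kept in 9 of 9 alternatives, whereas the order of middle S, late S and G2 changed among them. The folds with early, middle and late S sites were 1.56, 1.81 and 1.70 in G1, 1.88, 2.11 and 2.03 in early S, 2.31, 2.58 and 2.42 in middle S, 2.34, 2.60 and 2.45 in late S and 2.27, 2.53 and 2.36 in G2. For pSIRT1 the highest folds were in early S, 1.87, 2.41 and 2.36, and the lowest in middle S, 1.13 (1.07 to 1.19), 1.41 and 1.40. The early S maximum was kept in 9 of 9 alternatives and the middle S minimum in 6, not with equal list lengths, the higher-scoring 50% of peaks or peak middles. As shares of peaks the order was another: 15.6, 21.8 and 20.7% of early S peaks overlapped early, middle and late S sites, against 19.5, 23.7 and 21.1% of late S peaks. The early S maximum was thus relative to low shares of relocated peaks, 8.31 to 9.04%, in a list of narrow regions. Differences between phases were not tested. The fold of pSIRT1 in middle S with early S sites fell to 0.964 when peaks within 1 kb counted as overlapping. In all 10 ChIP lists the early S sites gave the lowest fold of the 3 fractions, in the main comparison and in each of the 9 alternatives. The middle S sites gave the highest in all 10 lists of the main comparison, but with equal list lengths only in 2 of them, and the late S sites in 8. Accordingly pSIRT1 and pMCM2 of early S overlapped sites of their own phase less than sites of the other phases, by log2 folds of -0.35 (-0.38 to -0.32) and -0.13 (-0.16 to -0.11), and those of middle S overlapped their own phase more, by 0.16 (0.13 to 0.20) and 0.12 (0.10 to 0.14). In late S the differences of 0.012 (-0.0073 to 0.030) and -0.011 (-0.035 to 0.012) were not called.

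**Figure D3:**
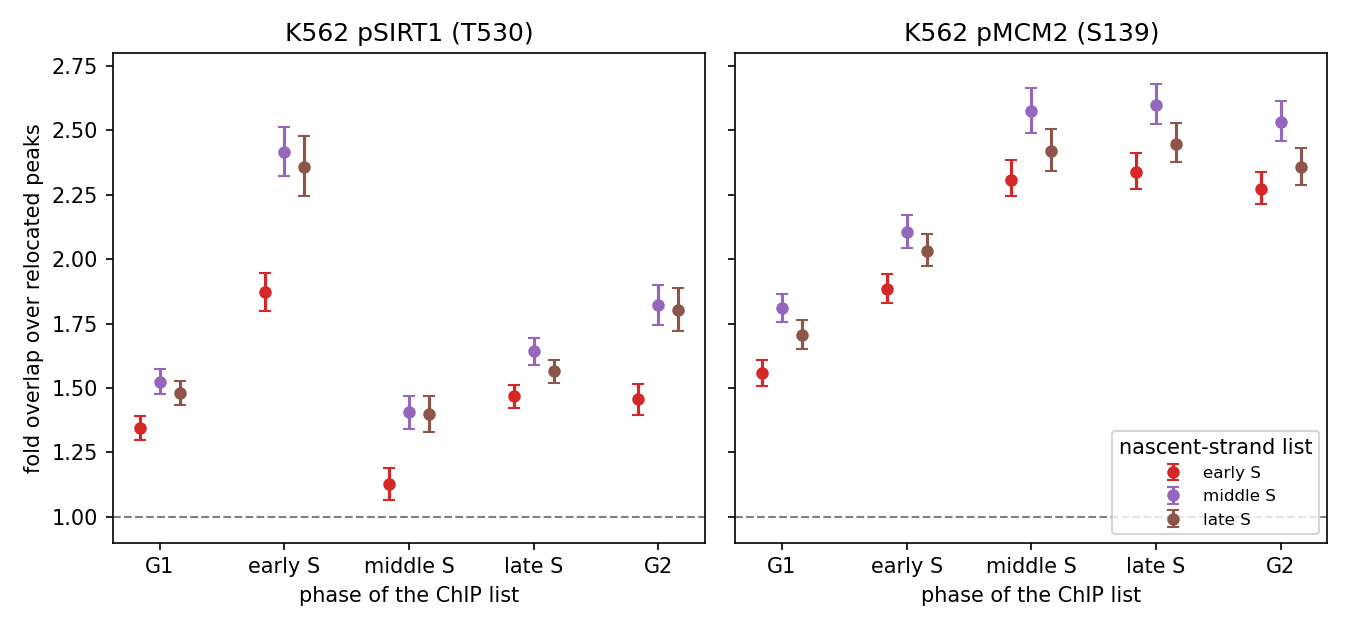
Fold overlap of K562 pSIRT1 (left) and pMCM2 (right) peaks of each cell cycle fraction with early, middle and late S nascent-strand sites, relative to relocated peaks, where 1 (dashed) is chance. Points are single libraries with 95% intervals from resampling 5 Mb genome blocks, and pMCM2 folds with middle S sites are lowest in G1 at 1.81 and lie between 2.53 and 2.60 from middle S to G2, while the highest pSIRT1 fold with them is 2.41 in early S.

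pSIRT1 and pMCM2 lay together in each K562 phase. The fold was 2.46 (2.34 to 2.59) in G1, 5.08 (4.82 to 5.34) in early S and 2.66 (2.51 to 2.81) in middle S. It was 2.71 (2.58 to 2.84) in late S and 3.12 (2.96 to 3.27) in G2. As shares, 16.9, 22.1, 29.9, 20.7 and 32.5% of pSIRT1 peaks overlapped pMCM2 from G1 to G2, so the share was highest in G2. The early S fold was relative to the lowest share of relocated peaks, 4.34%. Between neighbouring phases pMCM2 lists overlapped with folds of 4.21 to 5.26 and pSIRT1 lists with folds of 1.98 to 4.79. The lowest pSIRT1 value (not as an odds ratio) was that of middle with late S, where 93.9% of middle S peaks overlapped the long late S list. Of the G1 peaks, 8600 of 75682 for pSIRT1 (11.4%) and 3486 of 24359 for pMCM2 (14.3%) were found in all 4 other phases. The highest ranked pSIRT1 regions present in all 5 phases were at 133789001 to 133840600 of chromosome 9, at 155195601 to 155206400 of chromosome 7 and at 45753401 to 45757000 of chromosome 15, with 2749, 1058 and 6767 reads in G1. These counts were not compared with the genomic DNA controls here, so binding and local copy number cannot be told apart in this ranking. The pSIRT1 peaks of unfractionated cells overlapped the lists of G1, early S, middle S, late S and G2 with folds of 1.85 (1.77 to 1.93), 2.82 (2.66 to 2.99), 1.92 (1.81 to 2.04), 1.83 (1.75 to 1.90) and 2.31 (2.16 to 2.48). The fold was highest with early S, whereas the share of overlapping peaks was lowest there, 15.96% against 58.9% with late S, the longest list.

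Across the 2 cell lines, 43.8% of HCT116 pSIRT1 peaks overlapped pSIRT1 of unfractionated K562 cells, a fold of 1.73 (1.67 to 1.79). HCT116 nascent-strand sites overlapped those of K562 with folds of 1.65 to 2.04. The depleted list gave the lowest values, 1.65 (1.60 to 1.69) with early S, 1.73 with middle S and 1.77 with late S, and the aphidicolin list the highest, 2.01, 2.02 and 2.04 (1.99 to 2.097). The depleted list was lowest in 8 of 9 alternatives, not with the higher-scoring 50% of peaks, and the aphidicolin list highest in 7, not with peak middles or without chromosomes 5 and 21. Of the 93 planned overlaps between lists and site classes, 93 had an interval above 1, and the lowest fold was 1.13.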

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

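K562 peak numbers of the 2 antibodies moved in opposite directions from G1 in early S, middle S and G2, each with 1 library per phase, and the difference between the antibodies was not tested, nor was any test added after it was seen. From G1 to early S the number of pSIRT1 regions fell to 0.480 of its G1 value while that of pMCM2 rose to 1.79 times. In middle S the values were 0.338 and 1.45, and in G2 0.606 and 3.40. In late S both lay above G1. Reads did not follow the region number in early S, where pSIRT1 regions held 4935710 reads against 3097598 in G1, at 215 against 18.1 reads per kb over 0.134 times the covered length. The pSIRT1 lists of middle S and G2 hold scores where the other K562 lists hold read counts. Their signal per region could therefore not be set beside that of G1. Whether their regions were called as those of G1 were is unknown, so their lower numbers cannot be told apart from a difference in peak calling. For pMCM2, reads in regions rose from 578108 in G1 to 4260082 in G2. Library depth is unknown, so the pMCM2 numbers cannot be told apart from depth.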

How the results depend on the processing

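Of 1025 alternative values, 1000 kept their side of the calling limit and, where the main value was called, their direction. Among them were 835 of 837 overlap folds, 117 of 135 differences of log2 folds and 48 of 53 peak number ratios. A value called in neither setting could change sign and still be counted among them. The odds ratios used the same counts as the folds, so the 93 odds ratios of overlaps were bound to keep their side and direction. Peak middles, odds ratios and leaving out chromosomes 5 and 21 were chosen after seeing the data. Where no reason is given, the cause of a change was not tested. By covered length the ratios of the depleted, T530A and aphidicolin lists to the wild-type rescue were 1.03, 0.922 and 0.845, since the wild-type rescue peaks were wider; among peaks above the median read count of the wild-type rescue the T530A and aphidicolin ratios were 0.920 and 0.824. For sites without minus with wild-type SIRT1, equal list lengths gave 0.010 for pSIRT1, -0.019 for pMCM2 and 0.022 for H4K16ac; odds ratios gave -0.38, -0.12 and -0.34; for pSIRT1, placement anywhere gave -0.0068 and peak middles -0.011. Early S with late minus middle S became -0.013 with relocation by 5 to 50 kb and 0.098 as an odds ratio. The own-phase difference of pSIRT1 in late S, not called, was called with the higher-scoring 50% of peaks (0.053), equal lengths (0.23), placement anywhere (-0.14) and relocation by 5 to 50 kb (0.029). That of pMCM2 in late S was called within 1 kb (-0.029), with the higher-scoring 50% (0.036), at equal lengths (0.096) and with placement anywhere (-0.088). pSIRT1 in middle S with early S sites gave 0.964 within 1 kb and 1.096 (0.986 to 1.22) with placement anywhere. A common score limit could not be applied to pSIRT1 in middle S and G2, whose lists hold scores. GC-matched relocation, promoter overlap, gene lists and sequence content were not run. No paired analysis was possible because each group has 1 library. Library depth is unknown, and peak numbers move with it.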

Other observations

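The classes of sites without and with wild-type SIRT1 were planned. The K562 site classes, the classes of depleted-list sites by number of other lists and the further pairs were chosen only after the result each bears on was seen. So were the tests of reads at shared peaks of equal width, of SIRT1 protein and of an effect of phosphorylated SIRT1 alone. The same holds for the tests of chromosome density beyond pSIRT1 of early S and for the matching of sites on width and reads. K562 nascent-strand sites were divided by the S fractions they were seen in. At the middles of the 30537 middle S sites shared by all 3 fractions, pMCM2 folds were 2.68 (2.53 to 2.83) in G1, 3.12 in early S and 4.27 to 4.42 from middle S to G2, and pSIRT1 of early S reached 4.23 (3.91 to 4.56). At the 20174 sites of early S alone, pSIRT1 lay below chance in G1 (0.871), early S (0.811), middle S (0.476) and G2 (0.614) but not in late S (1.04, 0.990 to 1.09) or unfractionated cells (0.9745, 0.927 to 1.02), while pMCM2 lay above chance in early S, middle S, late S and G2 (1.19 to 1.60). At the 17552 sites of middle S alone, pSIRT1 folds were 1.46, 2.90, 1.25, 1.73 and 1.79 from G1 to G2, and pMCM2 folds 1.78 to 2.84. At the 27191 sites of late S alone, pSIRT1 folds were 1.27, 2.64, 1.12, 1.32 and 1.72 from G1 to G2. Early-only minus late-only sites differed in log2 fold by -1.70 (-1.96 to -1.44) for pSIRT1 of early S and by -0.53 (-0.70 to -0.37) for pMCM2 of early S. Sites of all 3 fractions were wider and held more reads, 2400 bp and 86 against 1800 bp and 49 to 56. Sites of early S alone were selected for absence from the middle and late S lists. Those lists gave higher folds than the early S list with each fractionated K562 ChIP list. Low folds at early-only sites and negative differences to late-only sites were therefore favoured by how the classes were made.

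In HCT116 cells, depleted-list sites found in all 3 other nascent-strand lists carried pSIRT1 at 61.7% of their middles, a fold of 2.85 (2.71 to 2.99), against 34.8% and 2.46 (2.34 to 2.58) for sites in none of them. The folds of these 2 classes were 2.73 and 2.56 for pMCM2, a log2 difference of 0.096 (0.045 to 0.15), and 2.43 and 2.44 for H4K16ac. The classes also differed in median width and reads, 4000 bp and 185 against 1800 bp and 75, and were not matched on these. Among K562 pSIRT1 lists, early S and G2 stood apart by fold: 81.7% of early S peaks overlapped G2, a fold of 14.5 (12.5 to 17.02) over a relocated share of 5.62%. The shares and folds of early S peaks were 65.9% and 4.77 with G1, 63.9% and 3.14 with late S and 28.6% and 3.87 with middle S. Chromosomes 19 and 22 held 1.46 to 1.96 times the average density of nascent-strand peaks in the 4 HCT116 lists, but in K562 early S 0.755 (0.593 to 0.930) and 0.591 (0.440 to 0.729) times. In middle S the densities were 0.956 (0.753 to 1.18) and 0.744, and in late S 0.663 and 0.518. Chromosome 4 held 0.262 to 0.285 times the average in the 3 K562 nascent-strand lists. The HCT116 pMCM2 list had 0.433 times the average density on chromosome 3 and 0.461 on chromosome 18, where the other 6 HCT116 lists had 0.759 to 0.957 and 0.815 to 0.958. It was denser on chromosome 12, at 1.40 against 0.950 to 1.09, and on chromosome 1, at 1.42 against 1.15 to 1.21.

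Both rescue lists held more peaks on the first 50 Mb of chromosome 5 and on chromosome 21. The aphidicolin list, from cells with SIRT1, held 0.854 (0.782 to 0.945) times the peaks of the depleted list there, but presence of SIRT1 protein cannot be told apart from fewer copies in those cells, which would lower this ratio too, or from the drug. Extra copies in the rescue lines alone were predicted beforehand to raise reads at shared peaks there by a log2 value above 0.2, and this was met, the smallest of 4 shifts being 0.34. Peaks of equal width were compared only after that value was seen, and there the shift against the depleted list was 0.024 (-0.053 to 0.090) for the wild-type and 0.025 (-0.054 to 0.11) for the T530A rescue, so the first verdict was changed and such copies cannot be told apart from an effect of peak width. Against the aphidicolin list, the shifts at equal width were 0.40, 0.39 and 0.40 for the wild-type rescue, T530A rescue and depleted lists, the smallest being 0.39 (0.31 to 0.46), as extra copies in the depleted line and both rescue lines would give. A candidate explanation is that these 3 lines share extra copies relative to the aphidicolin-treated cells, but this leaves the lower peak number of the depleted list there unexplained, and differences in peak calling were not tested.

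Sites without wild-type SIRT1 had higher folds with pSIRT1, pMCM2 and H4K16ac than sites in both rescue lists. An effect of phosphorylated SIRT1 alone would make the pSIRT1 difference larger than the mean of the others, and it was smaller, by a log2 value of -0.041 (-0.043 with its interval of -0.064 to -0.022 in a repeat with other relocations). It was below 0 in 8 of 9 alternatives, from -0.0091 to -0.15, and at matched sites (-0.028, -0.053 to -0.0024), but 0.0085 with equal list lengths, so such an effect cannot be told apart. Width and reads may account for it: with 17329 sites of each class matched on both, the pSIRT1 difference became -0.083 (-0.12 to -0.046), and those of pMCM2 and H4K16ac -0.061 and -0.049. After matching, 64.1% of sites without and 68.0% of sites with wild-type SIRT1 carried pSIRT1. The difference in overlap with aphidicolin sites, -0.26 before matching, was -0.53 (-0.57 to -0.49) after it. Matching did not remove the selection of these classes by their presence in the wild-type rescue list.

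Early S nascent-strand sites overlapped the 10 fractionated K562 ChIP lists least. Dense chromosomes are argued against as the whole source: without chromosomes 17, 19 and 22 the early minus middle S difference of pSIRT1 in early S was -0.38 (-0.41 to -0.34), and without the 5 densest chromosomes of each list the difference was below 0 by more than its interval in 10 of 10 lists, from -0.39 to -0.16. A property of the early S list itself is consistent with the HCT116 lists: in 3 of 3 ChIP lists of unsynchronised HCT116 cells, early S sites also gave lower folds than middle S sites, with log2 differences of -0.15, -0.11 and -0.084. The early S list also held the fewest reads per kb of peaks, 33.1 against 37.4 in middle S and 35.0 in late S. Its weaker signal and a biological difference of early S start sites that both cell lines share both stay open. Neither was tested.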
